A study of Mus musculus with 12 samples.

How the data were processed

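Bone marrow cells of 8-week-old mice on a C57BL/6 background were grown with GM-CSF at 20 ng/ml and the semi-adherent dendritic cells were taken on day 7, per the labels' protocols. Cells of Arc/Arg3.1 knockout and wildtype animals received medium or LPS at 100 ng/ml for 30 min, were washed, and stayed in medium for 1 h before RNA was taken. Total RNA was labelled with an Affymetrix whole-transcript kit and hybridised to 12 arrays, 3 for each of 4 groups. The labels call the arrays of a group biological replicates and do not say whether their cultures came from separate animals, so p-values measure the spread between these cultures.

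The deposited table holds 1 log2 signal per probe set and array, already normalized by the authors. The background correction and normalization behind these log2 values are not given in the sources used here. The only tool in the submitters' processing notes is limma, without a version. Of 34390 probe sets, 23521 carried 1 gene in the platform annotation, 1814 carried several and 9055 carried none. Probe sets with several genes or none stayed out of the tests of genes. Where several probe sets carried 1 gene (1082 genes), the probe set with the highest mean over the 12 arrays stood for it, which left 22180 genes. Of these, 21994 (99.2%) were found in a reference gene table of assembly GRCm38.p6, used only for names and for the order of neighbouring genes. Which part of the Arc transcript the probe set covers is not given in the sources used here. On arrays, the number of arrays limits the precision.

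The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group, contrasts and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. There were 6 contrasts: LPS in each genotype, knockout against wildtype without LPS, after LPS and over both treatments, and the interaction of genotype and LPS. All groups shared 1 estimate of the spread.

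A departure from this plan was made after the values were seen. The 3 untreated wildtype arrays differed from each other by less than any other pair of arrays of 1 group, with values in the report. Their mean was therefore counted as 1 sample, although the labels call them biological replicates, and the fit has 10 samples and 6 residual degrees of freedom. The counts with 12 separate samples, as planned, had been seen when this was decided, and the counts with 10 samples had not. The counts with 12 samples are given beside the main ones throughout. In groups left with 1 sample, that sample is assumed to vary like those of the other groups.

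Named genes were Arc in each comparison and, per contrast, up to 12 genes with the largest increase and up to 12 with the largest decrease. Each had to pass the threshold, with every array of the higher group above every array of the lower one (within each treatment for the comparison over both, and without this condition for the interaction). Predicted genes, small RNA genes and symbols ending in Rik were left out, and where no gene passed, the 5 with the smallest p were named, predicted genes among them. For each gene list, up to 4 members past the threshold were taken, or the 2 with the smallest p. A gene outside this rule is said to be chosen after its values were seen.

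Of 652 symbols on 32 gene lists, 597 were measured, and 31 lists had the minimum of 5 measured members. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, with adjustment over the 31 lists of a contrast. Camera with an estimated correlation and fry were alternatives. Single genes were also put to an exact permutation test, two-sided, where a group pair had 3 samples each or regroupings within treatment could be counted.

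The replicate numbers were checked for pairing through the correlation of residuals of arrays with the same number. Between untreated and LPS-treated knockout arrays these were 0.381, 0.299 and 0.196, and between the 2 LPS groups 0.338, 0.358 and 0.228. Between LPS-treated wildtype and untreated knockout arrays they were 0.145, 0.196 and 0.175. All exceeded 0.1, so numbers paired the samples in these comparisons, as a result from the data, since the labels do not say what a number shares. Between untreated and LPS-treated wildtype arrays they were -0.028, 0.0087 and -0.017, and between the untreated groups -0.0090, -0.053 and -0.020, so numbers did not pair these. Between untreated wildtype and LPS-treated knockout arrays they were 0.089, 0.113 and 0.015, not all above 0.1, so pairing was not established there.

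Beside the main setting, 31 others were run. Of these, 25 were fixed before the data were examined: replicate blocks, another quantile normalization, a shift of each array to the same median, a filter that keeps genes above the median mean signal, all probe sets, trend and robust estimation, array weights, only the groups compared, a fold minimum of 1.5, other list tests, and leaving out each array. The other 6 were added after seeing the data. They were a term for or removal of 3 arrays with signal from Y-linked genes, a term for or removal of 4 arrays with low small RNA signal, a block in fits of 2 groups, and 12 arrays as 12 samples. The last is the fit planned before the data were examined, which became an alternative when 10 samples were counted.

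The procedure was tested on simulated data with 200 of 22180 genes changed. Of 50 genes changed 2-fold, it recovered 24 for LPS in wildtype, 34 for LPS in knockout, 31 for the knockout without LPS and 42 for the knockout after LPS. Where genes were changed only in LPS-treated knockout samples, 14 of 50 were recovered at 2-fold in the comparison over both treatments and 16 in the interaction. At 4-fold these were 43 and 42. In these simulations 108 to 160 genes were called, which makes the adjustment less strict than where 0 to 3 genes pass. The recoveries can therefore overstate the power of the genotype and interaction comparisons, where few or no genes passed. The number of deposited value columns left unused was 0.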

Results

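Gene expression was measured in bone marrow-derived dendritic cells, antigen-presenting cells grown from marrow with the growth factor GM-CSF, of mice lacking Arc (Arc/Arg3.1) and of wildtype mice. Arc is an immediate early gene best known from neurons, where its protein acts in receptor endocytosis at synapses. Cells were left untreated or given LPS, a bacterial cell wall component that activates Toll-like receptor 4, in 4 groups of 3 arrays. The series title relates Arc to migrating dendritic cells and to actin dynamics. The median log2 signal per array lay between 6.50 and 6.67.

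The targeted gene separated the genotypes on every array. Arc had a log2 signal of 9.21 to 9.62 on the 6 wildtype arrays and 7.68 to 8.05 on the 6 knockout arrays. The group values were 9.39 in untreated wildtype cells (1 counted sample), 9.40 ± 0.20 in LPS-treated wildtype cells, 7.91 ± 0.125 in untreated knockout cells and 7.91 ± 0.20 in LPS-treated knockout cells (SD, n = 3 each). Over both treatments, Arc was 2.80-fold lower in the knockout (log2 -1.49, SE 0.12, adjusted p = 0.0015 by limma, lower on 6 of 6 knockout arrays). The exact permutation p within treatment was 0.0125, the smallest that 80 regroupings can give. Which part of the transcript the Arc probe set covers is not known here, so the remaining signal cannot be read as remaining transcript. LPS left Arc at a log2 difference of 0.01 (SE 0.20) in wildtype and -0.01 (SE 0.14) in knockout cells, with adjusted p = 0.997 and 0.990.

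**Figure D1:**
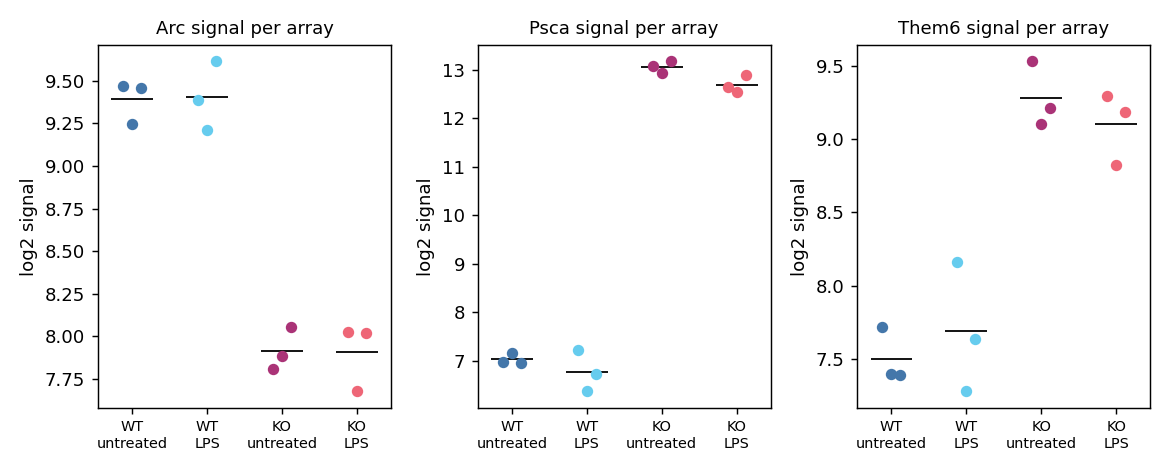
Log2 signal (vertical axes, not starting at 0) of Arc, Psca and Them6 on the 12 arrays, by group; each point is an array and each line the mean of 3 arrays. Arc lies at 7.68 to 8.05 on knockout and 9.21 to 9.62 on wildtype arrays, and Psca at 12.53 to 13.17 on knockout and 6.38 to 7.23 on wildtype arrays.

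The 3 untreated wildtype arrays were much alike. Over 6440 genes with a mean log2 signal above 8, the SD of the differences between 2 of these arrays was 0.105 to 0.108, and 0 genes differed by more than 2-fold. In the other 9 pairs of arrays of 1 group, this SD was 0.193 to 0.438, and 7 to 303 genes differed by more than 2-fold. The median variance per gene was 4.03 to 8.99 times higher in the other groups. Over all genes tested the gap was smaller, with an SD of 0.226 to 0.232 for these arrays and 0.247 to 0.435 in the other 9 pairs. These arrays differed by less than any other pair of replicates and were counted as 1 sample.

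**Figure D2:**
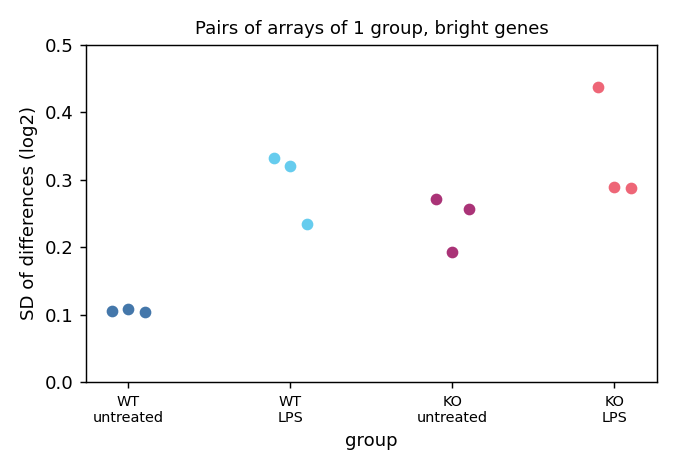
SD of the log2 differences between 2 arrays of the same group over 6440 genes with a mean log2 signal above 8 (vertical axis), by group; each point is a pair of arrays. Pairs of untreated wildtype arrays lie at 0.105 to 0.108 and the other 9 pairs at 0.193 to 0.438.

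Sex-linked genes went against the label on most arrays, since all animals are labelled male. Xist, the transcript of the inactive X chromosome in females, was at 11.22 to 11.92 on 9 arrays, where the Y-linked genes Kdm5d, Uty and Eif2s3y were at 3.33 to 4.86. On 3 arrays (untreated knockout replicate 2, LPS-treated knockout replicate 2 and LPS-treated wildtype replicate 1), Xist was at 5.63 to 5.76 and these Y-linked genes at 8.14 to 9.89. The median signal of 84 small nucleolar and other small RNA genes was 9.66 to 9.84 on replicates 2 and 3 of both LPS groups and 10.43 to 11.04 on the other 8 arrays. Both splits were chosen after the values were seen, and each count was repeated with them.

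**Figure D3:**
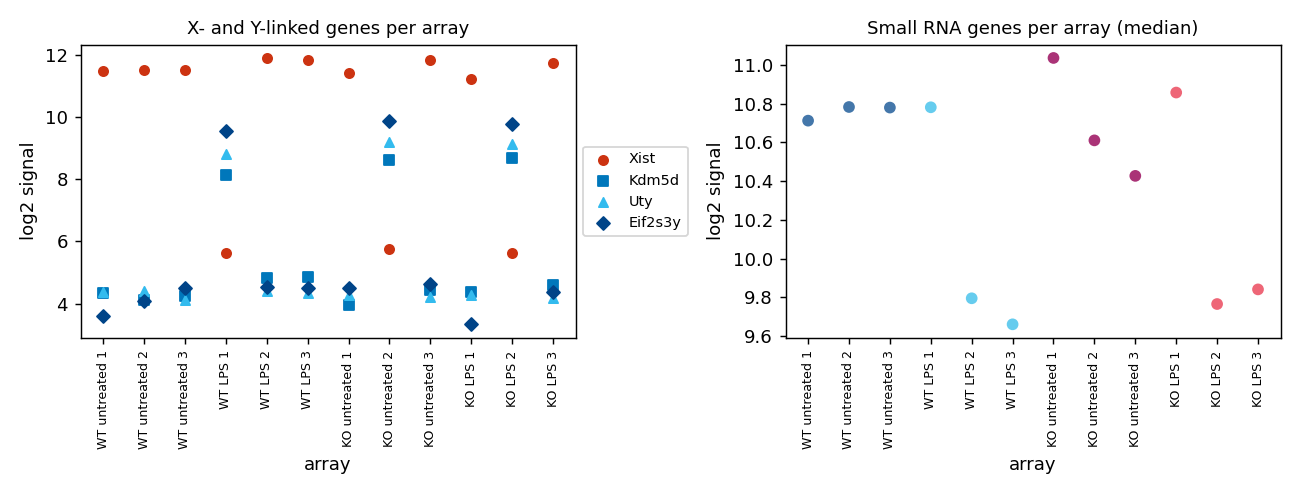
Log2 signal of Xist and of the Y-linked genes Kdm5d, Uty and Eif2s3y (left) and median log2 signal of 84 small RNA genes (right) on each of the 12 arrays; vertical axes do not start at 0. Xist is at 5.63 to 5.76 on 3 arrays and 11.22 to 11.92 on 9, and the small RNA median is at 9.66 to 9.84 on 4 LPS arrays and 10.43 to 11.04 on the others.

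The response of wildtype cells to LPS was led by inflammatory mediators. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose 43.4-fold (log2 5.44, SE 0.41, adjusted p = 0.000149 by limma). The cytokine genes Il1a, Tnf and Il23a rose 25.7-fold, 20.6-fold and 16.8-fold (SE 0.39, 0.38 and 0.17 on the log2 scale). The chemokine genes Cxcl10, Cxcl2 and Ccl4 rose 24.9-fold, 15.9-fold and 12.5-fold (SE 0.40, 0.44 and 0.38), and Ccl3 by 3.70 on the log2 scale (SE 0.41). Rasgef1b (26.3-fold), Acod1, which makes itaconate (18.1-fold), Nfkbiz, an NF-kB cofactor (15.8-fold), and Serpinb2 (15.3-fold) also rose, with adjusted p from 4.45e-05 to 0.0058. Among genes that fell, Ccr2, the receptor that draws monocytes to inflamed tissue, was 2.90-fold lower (log2 -1.54, SE 0.27, adjusted p = 0.0171), and Arrdc3 was 2.99-fold lower (log2 -1.58, SE 0.28). Zfp759 was 4.33-fold lower, and the granule genes Prg2 and Camp were 2.87-fold and 2.81-fold lower, as was the receptor gene Sirpb1a at 2.66-fold. The other 6 named genes that fell are odorant and vomeronasal receptors, Vmn1r103, Olfr293, Olfr1307, Vmn1r158, Vmn1r64 and Olfr339, at log2 -2.48 (Vmn1r103) to -1.57 (Olfr339). Of these, Olfr293, Olfr1307, Vmn1r64 and Olfr339 lie in both groups below the median of probe sets without a gene (5.89 to 6.09 over the samples), so their values cannot be read as changes in transcript. Vmn1r158 (5.82) and Camp (5.87) reach this level after LPS. Zfp759 (6.25), Prg2 (6.40) and Vmn1r103 (6.695) lie close to it after LPS, so their folds are also ratios of signals. The untreated signals of Ptgs2 (6.78), Cxcl10 (6.68), Il23a (6.33) and Serpinb2 (6.34) lie close to it, so their folds are ratios of signals and not of transcript amounts. The naming rule required all 3 LPS arrays of each gene in this paragraph on one side of all 3 untreated arrays, so this separation is no result.

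In all, 297 genes rose and 52 fell in wildtype cells, 349 of 22180 tested, with 3 LPS samples against 1 counted sample. At least 2-fold changes were 207 and 38 of them. With 12 arrays as 12 samples, 1195 rose and 722 fell. Without LPS-treated wildtype replicate 3 the count was 184, and without LPS-treated knockout replicate 3 it was 231. With a term for the 4 arrays of low small RNA signal, 208 rose and 44 fell. Without those arrays, only LPS replicate 1, an array with Y-linked signal, was left to compare with the counted untreated sample. The 24 named genes kept their direction there, which the naming rule had fixed in advance. The log2 change of Acod1 was 3.41 without those arrays and 3.29 with the term, against 4.18 in the main setting. In the fit of only these 2 groups the count was 196. The median 95% interval of a log2 fold change was ± 0.42.

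In wildtype cells, 4 gene lists were called higher with either correlation. Of 33 early inflammatory genes, 22 rose, 0 fell and 11 did not pass (26 rose when adjusted over the list alone), with adjusted p = 1.06e-46 by camera and adjusted p = 0.0062 with an estimated correlation. Of 29 immediate early genes, 15 rose, 0 fell and 14 did not pass (25 rose adjusted over the list alone), led by Nr4a1 (log2 3.38, SE 0.23), Fosb (2.59, SE 0.34) and Dusp2 (2.06, SE 0.20), with camera adjusted p = 1.50e-37 and adjusted p = 0.0230 with an estimated correlation. Of 20 negative regulators of Toll-like receptor and cytokine signalling, 11 rose and 9 did not pass (14 rose adjusted over the list alone), with Tnfaip3 at 1.94 (SE 0.19) and Socs3 at 1.48 (SE 0.25), and adjusted p = 0.0240 with an estimated correlation. Of 16 heat shock and handling stress genes, 2 rose, the chaperones Hspa1a (3.61, SE 0.34) and Hspa1b (2.27, SE 0.24), and Txnip fell (-0.99, SE 0.20); 5 rose and 1 fell adjusted over the list alone, and adjusted p = 0.0322 with an estimated correlation. 

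Other called lists in wildtype cells lost the call with an estimated correlation. Of 18 NF-kB subunits and feedback genes, 8 rose (12 adjusted over the list alone), with Nfkbid at 2.24 (SE 0.23), camera adjusted p = 2.06e-20 and adjusted p = 0.101 with an estimated correlation. Of 29 type I interferon response genes, 7 rose (8 adjusted over the list alone), among them Isg15 (2.97, SE 0.21), Ifit1 (2.48, SE 0.22) and Ifnb1 (2.22, SE 0.21), with camera adjusted p = 1.14e-05 and adjusted p = 0.317 with an estimated correlation. Of 25 dendritic cell maturation genes, 5 rose, such as the co-stimulatory genes Tnfsf9 (3.56, SE 0.20) and Cd40 (2.13, SE 0.20), while 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.33e-08, adjusted p = 0.164 with an estimated correlation). The receptor TLR4 and its adaptors (2 of 20 rose, Cd14 at 1.49, SE 0.28, and Map3k8 at 1.17, SE 0.16; 6 adjusted over the list alone) and cholesterol genes (2 of 14 rose, Insig1 at 1.53, SE 0.18, and Ch25h at 1.51, SE 0.19; 2 adjusted over the list alone) had camera adjusted p = 0.0037 and 0.0033. With an estimated correlation their adjusted p = 0.344 and 0.394.

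The neutrophil, inflammatory monocyte and macrophage marker lists were called lower in LPS-treated wildtype cells at the preset correlation alone. Of 18 neutrophil markers, 1 fell (7 adjusted over the list alone), with a list median of -0.90, camera adjusted p = 2.41e-06 and adjusted p = 0.317 with an estimated correlation. Of 9 inflammatory monocyte markers, Ccr2 fell (3 fell adjusted over the list alone), with a list median of -0.87, camera adjusted p = 1.14e-05 and adjusted p = 0.241 with an estimated correlation. Of 15 macrophage markers, 0 fell (0 adjusted over the list alone), with a median of -0.30, camera adjusted p = 0.0275 and adjusted p = 0.570 with an estimated correlation. The other 18 lists, on antigen presentation, other pattern receptors, Arc partners, chemokine receptors, adhesion, glycolysis, cell cycle, neighbours of Arc and further cell types, had camera adjusted p from 0.0736 to 0.975. Among them, 3 of 21 other pattern recognition receptors rose, Clec4e (2.10, SE 0.24), Nlrp3 (2.10, SE 0.32) and Tlr2 (1.37, SE 0.28), with 5 higher and 1 lower adjusted over the list alone; its median was -0.06 and its mean 0.12, so their signs differ (adjusted p = 0.670). Zbtb46 (0.88, SE 0.15) rose among 14 conventional dendritic cell markers (2 adjusted over the list alone) and Prg2 fell among 7 eosinophil markers (1 adjusted over the list alone). In the lists of MHC class I and II, glycolysis, cell cycle and Arc partners, 0 members passed (0 adjusted over the list alone).

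The response of knockout cells to LPS was led by nearly the same named genes. Ptgs2 rose 51.7-fold (log2 5.69, SE 0.29, adjusted p = 3.06e-06 by limma), Cxcl10 23.7-fold (SE 0.28), Rasgef1b 23.4-fold (SE 0.23), Cxcl2 22.9-fold (SE 0.31), Il1a 19.9-fold (SE 0.28) and Il23a 19.8-fold (SE 0.12, SE on the log2 scale). Nfkbiz, Tnf, Ccl4, Acod1, Serpinb2 and the co-stimulatory ligand Tnfsf9 rose 13.1-fold to 16.6-fold. The untreated signals of Ptgs2 (6.79), Cxcl10 (6.835), Il23a (6.39) and Serpinb2 (6.48) lie close to the median of probe sets without a gene. The folds of these genes are ratios of signals and not of transcript amounts. Ccr2 was 3.44-fold lower (log2 -1.78, SE 0.19). The zinc finger genes Zfp759, Zfp273 and Zfp975 were lower by log2 -2.11, -2.04 and -1.84. The LPS-treated signals of Zfp273 (4.72) and Zfp975 (5.72) lie below the median of probe sets without a gene (5.89 to 6.09) and give no fold of transcript. That of Zfp759 (6.29) lies close to this median. The immune receptor genes Sirpb1c, Cd200r1 and Tlr8 were 3.95-fold, 3.56-fold and 2.90-fold lower, Arrdc3 3.17-fold and 9930111J21Rik2 4.18-fold lower. The neutrophil granule and alarmin genes Ngp, Ltf and S100a8 were 3.23-fold, 2.89-fold and 2.80-fold lower, with adjusted p from 0.0210 to 0.0497. By the same rule, all 3 LPS arrays of each gene in this paragraph lay on one side of all 3 untreated arrays (n = 3 against 3), which is no result.

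In all, 661 genes rose and 650 fell in knockout cells, 1311 of 22180, of which 230 and 71 changed at least 2-fold. With 12 arrays as 12 samples, 872 rose and 1149 fell. Replicate numbers paired these samples: with the replicate number as a block 2312 genes passed, with it as a random block 2318, and with a block within genotype 1363. The count was 737, 764 and 657 without untreated knockout replicate 1, 2 and 3, and 615 without LPS-treated knockout replicate 3. With a term for the arrays of low small RNA signal 545 rose and 705 fell. Without those arrays, only LPS replicate 1 was left in the LPS-treated knockout group. The 24 named genes kept their direction there, which the naming rule had fixed in advance. Without those arrays, log2 changes were smaller for Acod1 (2.89, main 3.89), Cxcl10 (3.91, main 4.57), Il1a (3.67, main 4.32), Ccl4 (3.26, main 3.90), Serpinb2 (3.18, main 3.78) and S100a8 (-0.76, main -1.49, adjusted p = 0.148). They were larger for Sirpb1c (-2.77, main -1.98), 9930111J21Rik2 (-2.86, main -2.06) and Tlr8 (-2.13, main -1.53). With the block within genotype, 1021 of the 1311 genes stayed past the threshold. The median 95% interval was ± 0.30.

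In knockout cells, 3 lists were called higher with either correlation, of early inflammatory genes, immediate early genes and negative regulators. Of 33 early inflammatory genes, 25 rose and 8 did not pass (28 rose adjusted over the list alone; camera adjusted p = 2.01e-41, adjusted p = 0.0087 with an estimated correlation). Of 29 immediate early genes, 22 rose (25 adjusted over the list alone), with Nr4a1 at 3.41 (SE 0.16), and of 20 negative regulators 15 rose (16 rose and 2 fell adjusted over the list alone), with Socs3 at 1.77 (SE 0.17) and Il10 at 1.72 (SE 0.17); both lists had adjusted p = 0.0313 with an estimated correlation. Of 18 NF-kB genes 9 rose (12 adjusted over the list alone), and adjusted p = 0.196 with an estimated correlation. Of 29 interferon genes 10 rose (10 rose and 2 fell adjusted over the list alone), with Ifit1 at 2.88 (SE 0.16), and adjusted p = 0.357 with an estimated correlation. Of 25 maturation genes 8 rose and 1 fell (10 and 2 adjusted over the list alone), with Cd40 at 2.31 (SE 0.14), and adjusted p = 0.235 with an estimated correlation. Of 16 heat shock and stress genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the camera adjusted p of 0.0287 became adjusted p = 0.196 with an estimated correlation.

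Among cell type markers in knockout cells, 6 of 18 neutrophil genes fell (8 adjusted over the list alone) and 3 of 9 monocyte genes fell (6 adjusted over the list alone), Ccr2, Chil3 (log2 -1.48, SE 0.21) and Ms4a6c (-0.94, SE 0.16). Of 15 macrophage markers 1 fell, Lyz2 (-0.86, SE 0.15; 1 adjusted over the list alone). Camera gave adjusted p = 1.45e-05, 7.90e-05 and 0.0059 for these lists, and adjusted p = 0.397, 0.322 and 0.483 with an estimated correlation. Of 14 conventional dendritic cell markers, Zbtb46 (0.67, SE 0.10) and Irf4 (0.58, SE 0.11) rose (2 rose and 1 fell adjusted over the list alone), but the list was not called (camera adjusted p = 0.818). The 21 lists not called had camera adjusted p from 0.0674 to 0.935. Of 20 genes of TLR4 and its adaptors 6 rose and 1 fell (6 and 3 adjusted over the list alone), with Cd14 at 1.76 (SE 0.20) and Map3k8 at 1.14 (SE 0.11). Of 21 other pattern recognition receptors 4 rose and 3 fell (5 and 5 adjusted over the list alone), with Clec4e at 2.26 (SE 0.17), and of 14 cholesterol genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with Ch25h and Insig1 higher and Abcg1 at -0.75 (SE 0.11). Hdc (1.21, SE 0.30) rose among mast cell markers, Prg2 (-1.05, SE 0.18) fell among eosinophil and Lum (-0.48, SE 0.11) among stromal markers, each 1 gene also adjusted over the list alone. Among neighbours of Arc, Dennd3 (0.51, SE 0.13) rose and Ly6i (-0.68, SE 0.13) fell (1 and 1 adjusted over the list alone). For glycolysis, 0 members passed and 3 fell adjusted over the list alone.

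**Figure D4:**
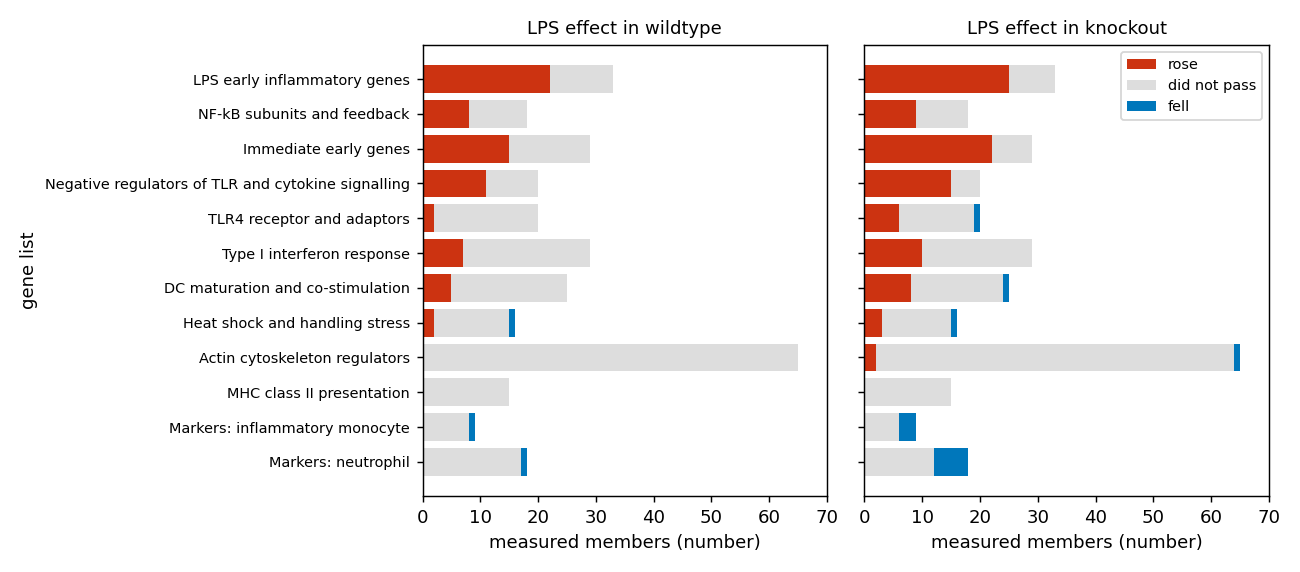
Number of measured members (horizontal axis) of 12 gene lists that rose, fell or did not pass the limma threshold after LPS, in wildtype (left) and knockout (right) cells. Of 33 early inflammatory genes, 22 rose in wildtype and 25 in knockout cells; of 65 actin regulators, 0 changed in wildtype and 3 in knockout cells.

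Genes that move cells and shape actin were examined because of the series title. Of 65 actin cytoskeleton regulators, 0 passed in wildtype cells after LPS (0 adjusted over the list alone), with Rhob at 0.81 (SE 0.19, adjusted p = 0.0668) and Vcl at 0.77 (SE 0.20, adjusted p = 0.122). The list median was 0.10, with camera adjusted p = 0.0212 and adjusted p = 0.581 with an estimated correlation. In knockout cells the GTPase gene Rhob (0.74, SE 0.13) and Vcl, which encodes the adhesion protein vinculin (0.74, SE 0.14), rose and the cofilin kinase Limk2 fell (-0.41, SE 0.10); 3 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.826). Of 40 adhesion and matrix genes, 3 rose in wildtype cells, Cd44 (1.34, SE 0.28), Itgav (1.25, SE 0.16) and Icam1 (1.08, SE 0.15), and 7 rose and 2 fell in knockout cells, with Mmp13 at 1.35 (SE 0.20) and Plaur at 1.29 (SE 0.32). Adjusted over the list alone, 7 rose in wildtype, and 8 rose and 4 fell in knockout cells. The list was not called in either genotype (adjusted p = 0.120 and 0.498), and its medians of -0.04 and -0.06 differ in sign from its means of 0.16 and 0.08. Among 19 chemokine receptors, Ccrl2 rose in both genotypes (2.79, SE 0.22, and 2.57, SE 0.16) and Ccr2 fell in both, while Ccr1 (-1.01, SE 0.19) and C3ar1 (-0.63, SE 0.16) fell in knockout cells. Adjusted over the list alone, 1 rose and 4 fell in wildtype and 3 rose and 4 fell in knockout cells, and the list was not called (adjusted p = 0.103 and 0.567).

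The LPS effects of the 2 genotypes, which share no arrays, were compared across genes. Pearson's correlation was 0.582 and Spearman's 0.319 over 22180 genes, which are not independent replicates. Over the 349 genes past the threshold in wildtype cells, Pearson's correlation was 0.908, the slope of the knockout effect on the wildtype effect was 0.801 and the median ratio was 0.909. These genes were selected on their wildtype effect, which has the larger error (median SE over all genes 0.19, against 0.13 in knockout). Both can lower the slope and the ratio, so a weaker response of knockout cells cannot be read from them. Both genotypes called 321 genes, all with the same sign, and of the 349 genes called in wildtype cells 330 had the same sign in knockout cells, whether called there or not; 292 of the shared calls were higher and 29 lower, where independent lists would share 8.85 and 1.52. The correlation over all genes was 0.444 without LPS-treated knockout replicate 2 and 0.673 without LPS-treated knockout replicate 1. Without the 4 arrays of low small RNA signal it was 0.311.

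**Figure D5:**
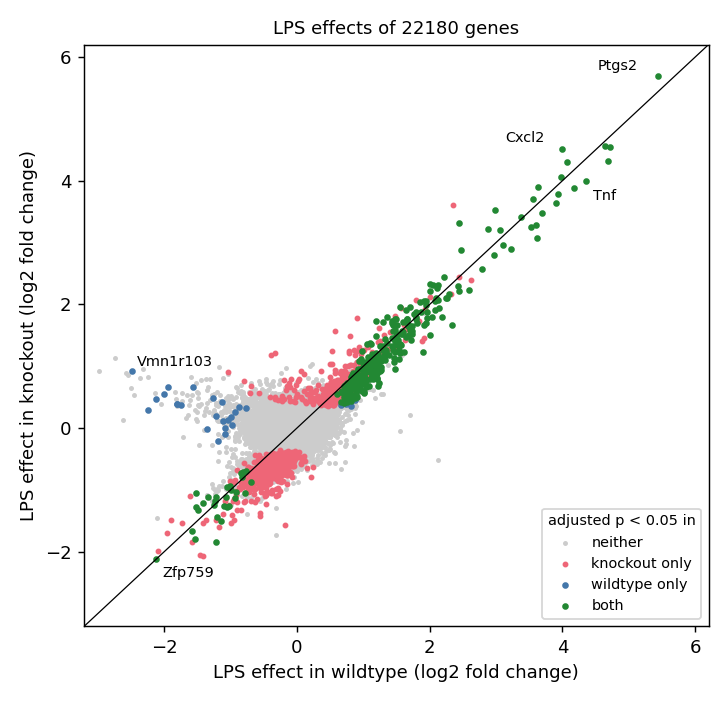
LPS effect (log2 fold change) of 22180 genes in wildtype (horizontal axis) and knockout cells (vertical axis); each point is a gene, coloured by the comparison in which its adjusted p passed 0.05, and the line marks equal effects. Ptgs2 lies at 5.44 and 5.69, and Vmn1r103 at -2.48 and 0.92.

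Knockout and wildtype cells without LPS differed in 1 gene past the threshold. Psca, which encodes a small membrane-anchored protein of the Ly6 family, was 64.98-fold higher in the knockout (log2 6.02, SE 0.27, adjusted p = 6.30e-06 by limma, higher on 3 of 3 knockout arrays). Its log2 signal was 13.06 ± 0.119 in knockout cells (SD, n = 3) and 7.04 in the counted wildtype sample. Wildtype signals of Psca are close to the median of probe sets without a gene (5.89 to 6.09) and were not shown to be above background, so its folds here and below are ratios of signals. Arc was at log2 -1.48 (SE 0.20) and missed the threshold (adjusted p = 0.177); it passed with the replicate number as a block (adjusted p = 0.0286), with array weights (0.00294) and with 12 arrays as 12 samples (0.00080), and over all settings its adjusted p lay between 0.00080 and 0.561. Of 22180 genes, 897 had an unadjusted p under 0.05, which is 4.04%. With 12 arrays as 12 samples, 6 genes were higher and 91 lower. With the replicate number as a block, which did not pair these samples, 3 passed: Psca, Arc and Them6 (1.78, SE 0.17, adjusted p = 0.0177), the last named after its value was seen. Without LPS-treated knockout replicate 1 the count was 2, the second being Gm6337 (-2.00, SE 0.22, adjusted p = 0.0477), named after its value was seen.

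After LPS, Psca was 59.99-fold higher in knockout cells (log2 5.91, SE 0.19, adjusted p = 2.01e-07 by limma), at 12.69 ± 0.183 against 6.78 ± 0.43 (SD, n = 3 each). Arc was 2.82-fold lower (log2 -1.50, SE 0.14, adjusted p = 0.0059). Both genes parted all 3 knockout from all 3 wildtype arrays, with an exact permutation p of 0.1 each, the smallest that 3 against 3 samples can give, so this design cannot reach 0.05. For Psca this parting was a condition of being named and adds no support. Psca and Arc were the 2 genes past the threshold (877 had an unadjusted p under 0.05), and 2 passed with 12 arrays as 12 samples. Replicate numbers paired these samples, and with the number as a block 4 genes passed; Them6 (1.41, SE 0.12) and the peptide transporter gene Slc15a2 (-1.18, SE 0.13) joined, named after their values were seen. With the block in a fit of only these 2 groups, 3 passed, Psca, Arc and Them6 (adjusted p = 0.0198), and Slc15a2 did not. With 1 array left out, the log2 difference of Arc stayed at -1.59 to -1.38. Without LPS-treated wildtype replicate 1, Arc missed the threshold (adjusted p = 0.0565) and the count was 1. Arc also missed it in the fit of only these groups (adjusted p = 0.0547), without the 3 arrays with Y-linked signal (0.0943) and without the 4 arrays of low small RNA signal (0.399), the highest value of any setting, the lowest being 0.000697. Without the Y-linked arrays 5 genes passed, Psca, Them6 (1.78), Slc15a2 (-1.73), Vmn1r103 (1.86) and Btbd35f27 (1.33). With a term for the small RNA arrays 4 passed, Psca, Arc, Them6 and Vmn1r160 (0.92), both sets named after their values were seen.

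Over both treatments, 3 genes on chromosome 15 separated the genotypes. Psca was 62.4-fold higher in the knockout (log2 5.96, SE 0.17, adjusted p = 3.96e-08 by limma), Them6, a gene of the thioesterase superfamily, was 3.02-fold higher (log2 1.60, SE 0.19, adjusted p = 0.0298) and Arc 2.80-fold lower. Each parted 6 of 6 knockout from 6 of 6 wildtype arrays, with an exact permutation p of 0.0125, the smallest that 80 regroupings can give. Psca and Them6 could be named only if they parted these arrays, so for them the parting and this p add no support. Arc was set in advance. Psca and Them6 lie 4 and 5 annotated genes from Arc in assembly GRCm38.p6. The other 43 measured neighbours of Arc did not pass and lay between -0.35 (Ly6c2) and 0.34 (Dennd3). Of 53 listed neighbours 45 were measured, and Jrk is among those that were not. The nearest measured one was Adgrb1 (log2 -0.01), 2 annotated genes from Arc. The list of 45 measured neighbours, of which 2 were higher (2 adjusted over the list alone), was not called by camera (adjusted p = 0.0870) and was called by fry (adjusted p = 0.0397).

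The genotype comparison over both treatments gave 732 genes with an unadjusted p under 0.05, and 6 genes past the threshold with 12 arrays as 12 samples, the other 3 being Rpl3 (1.09), Mirlet7f-1 (0.71) and Olfr498 (-0.56), named after their values were seen. Rpl3 also lies on chromosome 15, 279 annotated genes from Arc. Them6 missed the threshold without untreated knockout replicate 1 (adjusted p = 0.0878), 2 (0.0716) or 3 (0.118), without LPS-treated knockout replicate 1 (0.0964) or 3 (0.139) and without LPS-treated wildtype replicate 3 (0.140), where its log2 difference was 1.53 to 1.64. It also missed with quantile normalization (adjusted p = 0.0965), all probe sets tested (0.123) and a term for the Y-linked arrays (0.0825). Without the arrays of low small RNA signal, Arc (adjusted p = 0.195) and Them6 (0.427) missed it. Over all settings the adjusted p lay between 1.23e-05 and 0.195 for Arc and between 0.000285 and 0.427 for Them6.

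No gene list separated the genotypes once the correlation between its genes was estimated. Without LPS, the 65 actin regulators had a median log2 difference of 0.11, higher in the knockout, with camera adjusted p = 0.0115 and adjusted p = 0.905 with an estimated correlation; 0 members passed (0 adjusted over the list alone), and Cfl2 (0.23, SE 0.14) and Actn1 (0.23, SE 0.16) had the smallest p. After LPS this list had a median of -0.01 and was not called (adjusted p = 0.958). Over both treatments it was at 0.04 with camera adjusted p = 0.0140 and adjusted p = 0.845 with an estimated correlation. The 21 measured genes of reported Arc partners and endocytosis were not called without LPS, after LPS or over both treatments (camera adjusted p = 0.350, 0.858 and 0.445), with 0 members past the threshold (0 adjusted over the list alone). For migration, the adhesion list (camera adjusted p = 0.400, 0.858 and 0.342) and the chemokine receptor list (0.0819, 0.745 and 0.271) were not called in these comparisons either. Their members did not pass, and Ccr8 (-0.74, SE 0.16, adjusted p = 0.592) was lower without LPS when adjusted over the list alone. Without untreated knockout replicate 1, 4 lists were called in the untreated comparison.

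After LPS, the interferon list (median 0.11, adjusted p = 0.000165) and the maturation list (median 0.09, adjusted p = 0.0025) were higher by camera in the knockout and the immediate early list lower (median -0.11, adjusted p = 0.0062). Each had adjusted p = 0.915 with an estimated correlation and 0 members past the threshold (0 adjusted over the list alone), with Ifit2 at 0.44 (SE 0.13), Cd40 at 0.29 (SE 0.14) and Maff at -0.47 (SE 0.16). Without LPS-treated knockout replicate 3, 0 lists were called, and without LPS-treated wildtype replicate 1, 7 were. Over both treatments, camera gave adjusted p = 0.000226 for maturation, 0.0018 for interferon, 0.0107 for NF-kB and 0.0114 for immediate early genes, the last one lower in the knockout. Each had adjusted p = 0.845 with an estimated correlation and 0 members past the threshold (0 adjusted over the list alone). Without LPS-treated knockout replicate 3, 1 list was called in this comparison, and without untreated knockout replicate 1, 8 were.

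Whether the response to LPS depends on Arc was tested as the interaction of genotype and LPS. No gene passed (0 of 22180 by limma), 982 had an unadjusted p under 0.05, and the median 95% interval of the difference was ± 0.52. The 5 genes with the smallest p were Gm15128, Gm3159 and the chemosensory receptors Olfr293, Olfr1307 and Vmn1r103, each with adjusted p = 0.217 and log2 differences from 1.55 to 3.40. Of the LPS-responsive genes, Il12a (0.36, SE 0.19) and Il1b (0.88, SE 0.48) had the smallest p in the inflammatory list. Among 65 actin regulators, Limk2 (-0.30, SE 0.17) had the smallest p, and the list was not called (adjusted p = 0.124), nor were the Arc partners (adjusted p = 0.558). Of 31 lists, 0 were called by camera with either correlation and 0 by fry, and without untreated knockout replicate 1 camera called 4.

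With 12 arrays as 12 samples, 55 genes passed the interaction test, all with a positive sign. Replicate numbers paired the knockout samples and the LPS groups, while pairing of the untreated wildtype arrays was not established. With the number as a block, 9 passed by limma (adjusted p = 0.0282 to 0.0478). These were Vmn1r103, Vmn1r94, Vmn1r188, Olfr1307, Olfr339, Olfr477, Gm3159, Gm15128 and Mir3475, named after their values were seen; with a block within genotype 0 passed. The count was 35 without LPS-treated knockout replicate 2 and 1 without untreated knockout replicate 1 (Olfr339, 2.50, SE 0.24, named after its value was seen). Without the arrays with Y-linked signal it was 6, and with a term for the small RNA arrays it was 2, Vmn1r160 (2.10) and Vmn1r103 (3.40), likewise named afterwards.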

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

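The tests on the position of Psca and Them6, on the stretch around Arc, on chemosensory receptor genes, on the likeness of the untreated wildtype arrays, on the genes of the highest split and on the 32 splits that part pairs were chosen after the result was seen, while the test of epithelial markers and the other splits of the samples were fixed before their result.

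Psca and Them6 were higher in knockout cells, by 62.4-fold and 3.02-fold. Epithelial cells in the knockout cultures, where Psca is a known surface antigen, are argued against: 18 of 20 markers were measured, their median log2 difference was -0.047 (range -0.22 to 0.16), 0 passed, and Epcam, Krt8 and Krt18 were at -0.04, -0.05 and -0.15. A local effect of the targeted allele stays open: 2 of 2 genes lie within 5 annotated genes of Arc, but this limit was set when their distances were known, so it tests nothing. Both belong to the list of 45 measured neighbours fixed before the data were examined, of which the other 43 did not pass. A stretch of donor strain DNA kept around the allele could also matter. Within up to 300 genes on each side of Arc, 8 of 583 had an unadjusted limma p under 0.01. At least as many were found in 8.02% of 212 overlapping stretches of other chromosomes (median 3, highest 13). This misses the 5% limit set before the share was computed. All 8 genes lie on the same side of Arc, 183 (Ift27) to 401 (Cyb5r3) annotated genes away. The share therefore does not describe the genes next to Arc, and this explanation stays open. An effect of the missing Arc protein on both genes stays open and was not tested.

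Chemosensory receptor genes (odorant and vomeronasal receptors) differed between the untreated groups with 12 arrays as 12 samples, where they made up 51 of 97 calls (52.6%, against 6.29% of tested genes), with a median log2 difference of -0.91. With array weights they made up 113 of 257 calls, all lower in the knockout. With the untreated wildtype arrays counted as 1 sample and equal weights, 0 of these genes passed by limma, while the median SE of those 51 genes went from 0.152 to 0.229 and their fold changes stayed; the call ended through the larger error, so whether 1 sample was counted as 3 cannot be told apart from a real difference. A level of dim probe sets that differs between arrays is a candidate explanation: over 10 samples the median of the 1394 chemosensory genes followed that of probe sets without a gene (Pearson's r = 0.853, permutation p = 0.0014; Spearman's rho = 0.867, permutation p = 0.0022; 1 relation computed). Without the 2 outermost samples r was 0.634, and over the 6 samples outside the arrays of low small RNA signal 0.928. The median of probe sets without a gene was 5.92 to 5.97 in untreated knockout samples and 6.07 in the untreated wildtype sample. The chemosensory median was 4.49 to 4.67 and 4.93 there, a larger gap, so the correlation does not account for the size of the difference. The permutations exchanged all samples freely, although replicate numbers paired the knockout and the LPS samples, so their p ignores this pairing. A genotype effect on these genes in untreated cells stays open.

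The 3 untreated wildtype arrays differed least of all groups. Of 9 other pairs of arrays of 1 group, 0 had a smaller SD of differences; this restates what was seen and is no test of whether 1 RNA was hybridised to 3 arrays, which stays open. Over genes with a mean log2 signal above 8, the smallest SD among the other pairs was 0.193, against 0.108 at most here. Over all genes tested it was 0.247, against 0.232 at most here. Separate cultures of unusual likeness remain possible, as the labels state, since no array is labelled as a repeat of 1 RNA.

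Several named genes moved in opposite directions in the 2 genotypes or treatments: measured from the mean of its comparison group, every sample of one group lay above 0 and every sample of the other below it. For both the LPS effect by genotype and the knockout effect by treatment, the log2 interaction values were 3.405 for Vmn1r103, 2.6012 for Olfr293, 2.5924 for Olfr1307, 2.1287 for Vmn1r64, 2.2314 for Olfr339 and 1.5483 for Gm3159. For the knockout effect by treatment alone they were 2.2031 for Vmn1r158 and 2.2006 for Gm15128. All of them hinge on 1 counted untreated wildtype sample. The group means of Olfr293 (2.89 to 5.01), Olfr1307 (3.76 to 5.70), Vmn1r64 (2.35 to 4.10), Olfr339 (2.67 to 4.24) and Gm3159 (4.58 to 5.71) lie below the median of probe sets without a gene (5.89 to 6.09), so their directions cannot be read as changes in transcript. In the main setting the interaction test of limma missed the threshold for all of them. With the replicate block Vmn1r103 (adjusted p = 0.0282), Olfr1307 (0.0351), Olfr339 (0.0351), Gm3159 (0.0434) and Gm15128 (0.0434) passed, and Vmn1r103 also with the term for the small RNA arrays (0.0337). Without the Y-linked arrays Vmn1r103 (0.0113) and Gm15128 (0.0208) passed, and over all settings the adjusted p of Vmn1r103 lay between 0.00146 and 0.733.

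Probe sets without a gene, which the comparisons do not use, also responded to LPS when all probe sets were tested. In wildtype cells 23 passed (8 higher, 15 lower) and in knockout cells 158 (84 higher, 74 lower), with 0 in the genotype and interaction comparisons by limma.

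Other splits of the samples were counted for 4 comparisons. For LPS in the knockout, 1 of 10 splits of the 6 samples gave as many genes (the real one, 1311; highest other 0), and for the knockout after LPS 1 of 10 (2 genes; highest other 0). Splits that part all pairs, 4 in each case, gave 0 at most beside the real one, and 10 splits are too few for a share under 0.05. For the genotype over both treatments, 2 of 80 splits within treatment gave 3 or more genes (the real one 3), so chance can be excluded only as a free exchange of the samples, which does not keep the pairs of replicate numbers. Of the 32 splits that part the LPS samples of each number, as the real one does, 1 gave as many, and the highest other gave 1. The highest of the other splits, which does not part these pairs, gave 16 genes, several times the real count, which points to a structure of the samples. It puts untreated knockout replicate 2, LPS-treated knockout replicate 2 and LPS-treated wildtype replicates 1 and 2 together, which are the 3 arrays of highest cell cycle signal and the 3 arrays with Y-linked signal. Its genes include Cdk1, Mad2l1, Cdkn3 and Cenpk of cell division and neither Xist nor the Y-linked genes read here. For the interaction, where the real count is 0 by limma (982 genes at an unadjusted p under 0.05), 80 of 80 splits give at least as many by construction, so this decides nothing about chance. The highest other count was 16. It comes from the same 4 sets of samples as the 16 genes above with the labels of the LPS sets exchanged, so it repeats that test and calls the same genes.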

How the results depend on the processing

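The settings that treat the Y-linked or small RNA arrays apart or block fits of 2 groups were chosen after seeing the data. The fit of 12 arrays as 12 samples was the planned one, and counting 10 samples in the main setting was chosen after seeing the data. The other settings were fixed before. No called value reversed its direction, while the LPS effects of Arc and its interaction, near 0 and not called, changed sign: without 1 array they were -0.09 to 0.11 in wildtype, -0.06 to 0.11 in knockout and -0.12 to 0.10 for the interaction. The naming rule had fixed the direction of the named LPS genes in settings that only leave out arrays. Psca passed in each genotype comparison under every setting, and Arc kept its sign there. Values outside 1.5 times the main count follow, and the cause was not tested unless a setting itself lowers the number of samples. Without the small RNA arrays, only replicate 1 is left in each LPS group.

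For LPS in wildtype (main 349), the count was 665 with the replicate block, 2297 with array weights, 196 with only the groups compared, 1917 with 12 arrays as samples, 76 without the small RNA arrays and 184 to 452 without 1 array. For LPS in the knockout (main 1311), it was 2312 with the replicate block, 2318 with a random block, 4698 with array weights, 2021 with 12 samples, 562 without the small RNA arrays and 615 to 1667 without 1 array. For the knockout without LPS (main 1), it was 3 with the replicate block, 257 with array weights, 97 with 12 samples and 1 to 2 without 1 array. After LPS (main 2), it was 4 with the replicate block, 15 with array weights, 1 with only the groups compared, 5 without the Y-linked arrays, 4 with a term for the small RNA arrays, 1 without them and 1 to 2 without 1 array. Over both treatments (main 3), it was 39 with array weights, 6 with 12 samples, 1 without the small RNA arrays and 2 to 3 without 1 array. For the interaction (main 0), it was 9 with the replicate block, 280 with array weights, 55 with 12 samples, 6 without the Y-linked arrays, 2 with a term for the small RNA arrays and 0 to 35 without 1 array.

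Array weights ran from 0.354 to 4.19. The replicate numbers did not pair the untreated wildtype arrays with LPS-treated wildtype or untreated knockout arrays. With LPS-treated knockout arrays, only number 2 exceeded 0.1 (0.113). In the block fit the counted untreated wildtype sample is a mean over its arrays and has no replicate number of its own. With this block the 349 and 1311 genes of the LPS comparisons all stayed past the threshold. With a block within genotype, 236 of 349 and 1021 of 1311 stayed. List tests made 32 calls over 6 comparisons, 52 without the Y-linked arrays, 7 with an estimated correlation, 16 with fry, 41 with the replicate block and 26 to 44 without 1 array. The Arc difference over both treatments was -1.42 (adjusted p = 0.195) without the small RNA arrays, where fewer samples remain, and -1.54 to -1.43 without 1 array. The correlation of LPS effects (0.582) was 0.829 over bright genes, 0.908 over genes called in wildtype, 0.457 without the Y-linked arrays, 0.311 without the small RNA arrays and 0.444 to 0.673 without 1 array. Arc has 1 probe set, so testing each Arc probe set gave no other value. Signal over background is not given in the deposited table, so dim probe sets could not be told from background.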

Other observations

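The test of gene families by symbol was chosen after the LPS effects were seen.

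Zinc finger genes named Zfp were frequent among genes that fell after LPS, but the family was not called with an estimated correlation between its genes (adjusted p = 0.145 in knockout and 0.493 in wildtype cells). Of 370 measured in knockout cells, 75 fell and 5 rose, that is 20.3% against 2.93% of all genes that fell (Fisher's exact test, two-sided, p = 3.27e-41, odds ratio 9.39, across genes that are not independent). In wildtype cells 9 fell and 2 rose (Fisher's exact p = 1.77e-07, also across genes that are not independent), and with arrays shifted to the same median 5 fell and 2 rose. Zfp759 (-2.12 in wildtype, -2.11 in knockout), Zfp975 (-1.21 and -1.84) and Zfp760 (-1.20 and -1.43) fell in both genotypes. The LPS-treated signals of Zfp975 (5.87 and 5.72) lie below the median of probe sets without a gene (5.89 to 6.09) and give no fold of transcript. Those of Zfp759 (6.25 and 6.29) lie close to this median. Among 130 families of genes sharing a symbol stem, camera gave the Zfp family adjusted p = 2.12e-10 in knockout and 0.000999 in wildtype cells at the preset correlation. The family median was -0.20 in knockout and -0.11 in wildtype cells, and it stayed below that of all genes with quantile normalization (-0.17 and -0.12) and with arrays shifted to the same median (-0.24 and -0.05). Without the 4 arrays of low small RNA signal, the family median was -0.22 in knockout and -0.08 in wildtype cells, with only LPS replicate 1 left in each genotype.

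Odorant (Olfr) and vomeronasal (Vmn) receptor families had the smallest camera adjusted p of the 130 families in wildtype cells, 6.73e-14 and 1.27e-11, both lower after LPS (median -0.26 each), but adjusted p = 0.594 and 0.509 with an estimated correlation. This rests on 1 counted untreated wildtype sample, which has the highest chemosensory median of the 10 samples (4.93, the others 4.49 to 4.85) and a median of 6.07 over probe sets without a gene (the others 5.89 to 6.09). In knockout cells the Olfr family was higher (median 0.12, adjusted p = 0.000306, and 0.823 with an estimated correlation) and the Vmn family was not called (median 0.08, adjusted p = 0.0840).

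Cell cycle genes varied between arrays within groups. Their median log2 signal was 8.70 on untreated knockout replicate 2, 8.73 on LPS-treated knockout replicate 2 and 8.54 on LPS-treated wildtype replicate 2. On the other arrays it lay between 7.17 and 8.02. Genes of mitochondrial ribosomal proteins named Mrpl had a median LPS effect of -0.31 in knockout cells, with 0 of 43 past the threshold, camera adjusted p = 4.39e-06 and adjusted p = 0.823 with an estimated correlation, and a median of -0.04 in wildtype cells (adjusted p = 0.751).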
